A study of Physcomitrium patens with 5 samples.

How the data were processed

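RNA sequencing was done on protonemata, the filamentous stage of the moss Physcomitrium patens, from a line in which PpARFC2 can be overexpressed by adding β-estradiol. Per the labels' protocols, protonemata aged 7 days were treated for 16 hours with 1 µM β-estradiol or with 0.01% DMSO. Total RNA was then extracted, poly-A RNA was selected with oligo-dT beads, cDNA was primed with random primers, and paired reads of 100 bp were sequenced on the DNBseq platform. The protocol describes no step that marks strand, so reads from overlapping genes on opposite strands are not separated here. There were 5 libraries, 2 from DMSO and 3 from β-estradiol, grouped by their titles. The columns of both tables were assigned to libraries by the column letters and replicate numbers that the labels give, and no column of sample values was left unused.

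The submitters' processing notes name HISAT2, StringTie, Cufflinks, Bowtie2 and RSEM. Their versions and roles, the genome build and the annotation are not given in the sources used here. The authors deposited an RPKM table of 31775 loci, with reads scaled per kilobase of locus and to a fixed library total. The authors also deposited a table named for TMM normalization, whose values are likewise scaled by locus length and library size. Each locus carries the authors' length in kilobases and a fraction named maxMultiRatio, deposited without a definition. It is 0 for 28723 loci and above 0 for 3052.

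RPKM multiplied by length was a whole multiple of a fixed step in each library for 100% of detected loci with a maxMultiRatio of 0, within 0.01 of a read. Over all detected loci the share was 91.6 to 92.6%. Only loci with a maxMultiRatio above 0 had fractional reads, and it is therefore treated as a mark of multiply mapped reads. Reads per locus recovered in this way summed to 17.6 to 27.7 M per library (M for mega). The totals behind the RPKM were 37.3 to 56.3 M, so 47.1 to 49.2% of them were in the listed loci. Loci with a maxMultiRatio of 0 and exactly 2 reads were more frequent than loci with 1 or 3 reads in every library (736, 369 and 217 in DMSO 1). Mates of a pair thus appear to have been counted separately, and reads are not independent molecules. The TMM table equals the recovered reads plus 0.5, divided by the reads in loci and a factor of 0.956 to 1.05 per library, and scaled by length.

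The locus IDs are not paired with gene names in the files, and 0 of 31775 IDs matched the reference table of 27567 genes used here. The 24 gene lists fixed before the data were examined (auxin, cytokinin, bud regulators, cell wall, photosynthesis, stress and others) were therefore not analysed here, nor was PpARFC2 itself. The naming rule fixed for that case was followed. It names the 2 loci with the largest increase and the 2 with the largest decrease among those past the threshold, with a mean of at least 1 RPKM in the higher group and no overlap between the groups. Regions are given by the ID prefix (Pp3c and a number, the chromosome in this ID scheme) and the locus number, and no base coordinates were used. Classes of loci by level, by reads in DMSO, by ID prefix and by neighbourhood were chosen after the data were seen. Loci singled out within them are described without an ID.

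Loci with a mean of at least 0.5 RPKM over the 5 libraries were tested (17429). The test was limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.5), two-sided, with trended and robust variance moderation and no covariate. Calls are loci with a Benjamini-Hochberg adjusted p under 0.05. All fold changes are on the log2(RPKM + 0.5) scale unless stated otherwise, which understates the change of low loci. An exact permutation of 2 libraries against 3 cannot go below p = 0.1, so single loci were tested only through the model. For rising loci with no read in either DMSO library the fitted fold is no bound. Medians are also given with these loci at an approximate lower bound, set by 3 reads over the DMSO group on the RPKM scale. Mates of a pair appear to be counted separately, so 3 reads stand for fewer than 3 pairs. The bound may therefore be too high. The fit was tested on simulated data for this comparison, with 200 of 17429 loci changed. It recovered 62.7% of 2-fold, 100% of 4-fold and 100% of 8-fold changes, and 2 of its 177 calls were false. The simulation gave all loci of a treatment the same spread, and its libraries shared no deviations across treatments. The real libraries differ in both respects, so these rates are not error rates of the calls reported here.

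The libraries fell into a deeper class (DMSO 1 and β-estradiol 1) and a shallower class (DMSO 2, β-estradiol 2 and β-estradiol 3), and induction was also measured within each class. Neighbouring pairs are tested loci next to each other by locus number under a prefix. Their number was compared with 10000 random reassignments of the calls among tested loci, or 1000 at wider spacing. Prefixes with at least 100 tested loci were tested with Fisher's exact test. Alternatives covered the pseudocount, the filter, the TMM table, scaling, variance moderation, the replicate number as a block and leaving out each library. After the data were seen, the depth class as a term, limma's voom on the recovered reads and a restriction to loci with a maxMultiRatio of 0 were added. The planned count models for deposited counts were not run, because neither table holds counts. Counting intervals are 95% and cover counting error only. Figures were drawn with matplotlib 3.10.9.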

Results

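The data set holds poly-A RNA profiles of Physcomitrium patens protonemata from an inducible PpARFC2 overexpressor line. Auxin response factors are transcription factors that bind auxin-responsive promoters, and PpARFC2 belongs to their class C. The line was treated with the inducer β-estradiol (3 libraries) or with the solvent DMSO (2 libraries). Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The DMSO libraries held 27.7 and 18.1 M reads in loci (M for mega), and the β-estradiol libraries 27.3, 18.7 and 17.6 M. Between 22049 and 23161 of the 31775 loci had at least 1 read in a library. At these depths, 3 reads in a locus of 1 kb correspond to 0.0533 to 0.0804 RPKM. The level of PpARFC2 was not analysed here, because the locus IDs are not paired with gene names in the sources used.

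β-estradiol libraries resembled each other more than DMSO libraries did. Across the 17429 tested loci, log2 levels of β-estradiol 2 and 3 correlated at r = 0.99, and both correlated with β-estradiol 1 at r = 0.97. The DMSO libraries correlated at r = 0.92, below the r = 0.93 between DMSO 1 and β-estradiol 1. Genes are not independent replicates, so these correlations describe the libraries and carry no p-value. The closest pair, β-estradiol 2 and 3, gave a chi-square of 2.76 per locus with the mates of a pair counted as 1 read, where counting noise alone gives 1 and the other pairs within a treatment gave 19.2 to 70.2. Preparation and amplification can exceed counting noise among repeats of 1 sample too, so this does not show that the pair are separate samples. The labels number them as replicates, and all 5 libraries were kept apart. If the pair were repeats of 1 sample, the tests below would count them as separate samples, and their p-values would be too small. Without β-estradiol 2 or without β-estradiol 3, limma called 32 loci changed at an adjusted p under 0.05, against 790 with both. The median SD of a locus was 0.27 on the log2 scale in DMSO (n = 2) and 0.14 in β-estradiol (n = 3). The first principal component (58.8% of variance) separated the treatments. The second (31.5%) separated DMSO 1 and β-estradiol 1, which have totals of 56.3 and 56.0 M reads, from the other 3 libraries, which have 37.3 to 39.4 M.

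**Figure D1:**
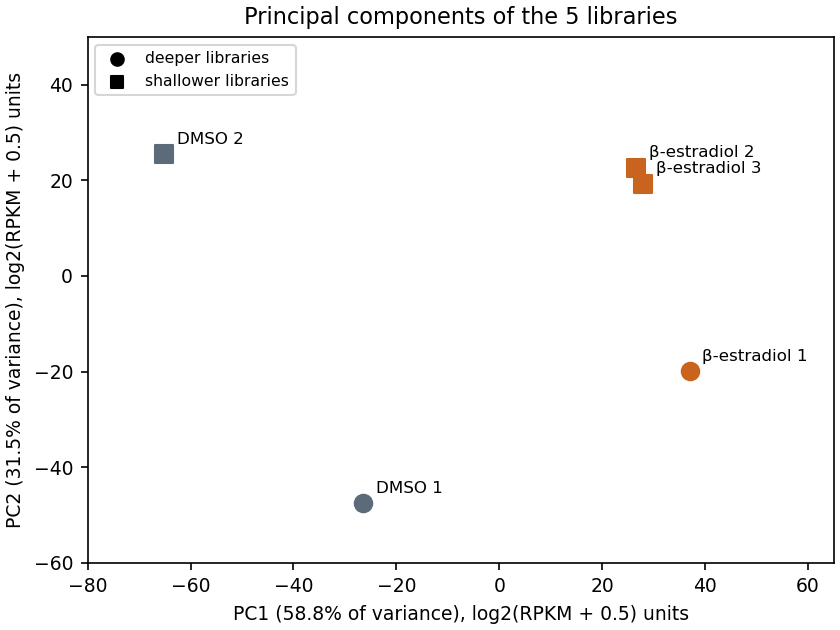
Principal components of log2(RPKM + 0.5) over 17429 tested loci, with a point per library (grey DMSO, orange β-estradiol; circles deeper, squares shallower libraries). The treatments separate along the first component (58.8% of variance), and the replicate 1 libraries from the others along the second (31.5%).

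The design asks which transcripts change after 16 hours of induction. All libraries come from the inducible PpARFC2 line, so effects of PpARFC2 and of β-estradiol itself cannot be told apart. Induction here means treatment with β-estradiol. In β-estradiol, 276 loci rose and 514 fell, together 790 or 4.53% of those tested (limma, adjusted p under 0.05). Loci that rose did so by a median of 1.18 on the log2 scale (quartiles 0.95 and 1.75), and 191 of them rose 2-fold or more. With the 7 of them that had no read in DMSO set to their bound, the median was again 1.18. Loci that fell had a median change of -1.41 (quartiles -1.86 and -1.10), and 429 of them fell 2-fold or more. Fitted changes of 8-fold or more were found for 14 loci that rose and 30 that fell. Loci without a read in DMSO entered this count at their fitted values, which understate their change. The loci that fell made up 3.11% of summed RPKM in DMSO and 1.02% in β-estradiol. The median change over all tested loci was -0.02. Without overlap between the groups were 7247 loci, or 41.6% of those tested, where chance gives 20%. The number of changed loci depended on which libraries entered the fit. It was 3762 without DMSO 1, 781 without DMSO 2, 134 without β-estradiol 1, 32 without β-estradiol 2 and 32 without β-estradiol 3. The loci that rose 2-fold or more numbered 574, 175, 49, 17 and 17 in these fits, and those that fell 2-fold or more 1273, 424, 85, 15 and 15. None of the 790 calls changed sign in them, and 28 passed in all of them, 16 higher and 12 lower.

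Changed loci were found at all levels of expression. Of the 4879 loci with a mean of 0.5 to 2 RPKM, 4.32% changed, 58 upward and 153 downward. Of the 9176 loci from 2 to 10 RPKM, 4.72% changed, 158 upward and 275 downward. From 10 to 50 RPKM, 4.74% of 2660 loci changed, 51 upward and 75 downward. At 50 RPKM and over, 2.80% of 714 loci changed, 9 upward and 11 downward. Loci with a maxMultiRatio above 0 accounted for 36 of the loci that rose and 74 of those that fell.

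Induction was then measured within each depth class, in libraries that share no sample and, with a single DMSO library in each, without a test. Across the tested loci, the change from DMSO 1 to β-estradiol 1 correlated with that from DMSO 2 to the mean of β-estradiol 2 and 3 at r = 0.71. All 790 calls had the same sign in both classes, as the test favours. Independently of the calls, 220 loci were higher by 2-fold or more in both classes, where unrelated lists would share 11.4. Another 566 were lower by 2-fold or more in both, against 64.6. With the depth class as a term in the model, 1708 loci rose and 2396 fell (limma, adjusted p under 0.05), and all 790 calls remained.

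**Figure D2:**
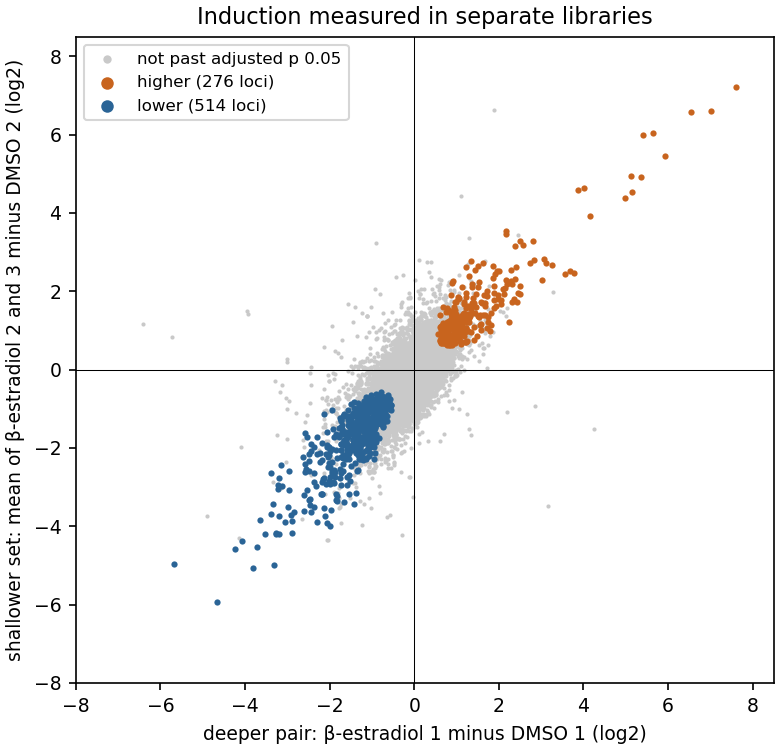
Change of each tested locus on the log2(RPKM + 0.5) scale in the deeper pair of libraries (horizontal axis) and in the shallower set (vertical axis); orange loci rose (276) and blue loci fell (514) in the fit of all 5 libraries, and grey loci did not pass. The measurements correlate at r = 0.71 across loci, and all 790 calls lie in the quadrants of equal sign.

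The largest increases went from near silence to high levels. Pp3c17_17250 (1.496 kb) rose from 0.293 ± 0.090 RPKM (SD, n = 2) in DMSO to 127 ± 34.8 RPKM (SD, n = 3) in β-estradiol. Its log2 change was 7.30 (SE 0.25, limma adjusted p = 0.000475), with 7.61 in the deeper and 7.21 in the shallower libraries. Pp3c6_7690 (0.315 kb) rose from 0.084 ± 0.118 RPKM (n = 2) to 64.4 ± 5.05 RPKM (n = 3). Its log2 change was 6.81 (SE 0.18, limma adjusted p = 0.000273), with 7.01 in the deeper and 6.61 in the shallower libraries. Only 2 reads fell on Pp3c6_7690 in both DMSO libraries together, against 2696 in the β-estradiol libraries. With the mates of a pair counted as 1 read (1 against 1348), the ratio at equal depth is 957, with a 95% exact (Clopper-Pearson) interval of 172 to 37820. Both loci have a maxMultiRatio of 0 and passed in all 18 alternative settings. Their order depends on the pseudocount: with 0.1 the log2 change of Pp3c6_7690 was the larger (8.62 against 8.33). Among rising loci without a read in DMSO, the highest approximate bound was 9.50 on the log2 scale of RPKM. Such a locus may have risen more than Pp3c17_17250, whose ratio of pooled RPKM was 434.

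In all, 16 loci that rose, Pp3c6_7690 among them, had at most 3 reads in each DMSO library, and 7 had none. They reached a median of 2.12 RPKM in β-estradiol, with a range of 1.11 to 64.4 RPKM. The reverse, at most 3 reads in each β-estradiol library, was seen for 1 locus that fell, from 1.90 RPKM in DMSO. The counts are not like for like, since the rule must hold in 3 β-estradiol libraries but in only 2 DMSO libraries. The filter on the mean over 5 libraries also asks a higher level of a locus silent in β-estradiol than of a locus silent in DMSO.

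The largest decreases were those of a pair of loci close together under Pp3c23. Pp3c23_1420 (1.194 kb) fell from 229 ± 76.8 RPKM (n = 2) to 6.65 ± 3.24 RPKM (n = 3), a log2 change of -5.09 (SE 0.49, limma adjusted p = 0.0108). It was -5.68 in the deeper and -4.97 in the shallower libraries. Pp3c23_1470 (1.766 kb) went from 56.0 ± 58.9 RPKM (n = 2) to 0.878 ± 1.03 RPKM (n = 3), a log2 change of -5.06 (SE 0.94, limma adjusted p = 0.0456). It was -4.67 in the deeper and -5.94 in the shallower libraries. Their maxMultiRatio, read here as a mark of multiply mapped reads, is 0.969 for Pp3c23_1420 and 1 for Pp3c23_1470, so their separate values are uncertain. The limma adjusted p of Pp3c23_1420 was 0.0602 without β-estradiol 2 and 0.0618 without β-estradiol 3, and 3.49e-05 to 0.0618 over all its alternatives. That of Pp3c23_1470 was 0.0737 without DMSO 2, 0.145 without β-estradiol 1, 0.17 without β-estradiol 2 and 0.114 without β-estradiol 3, and 0.000564 to 0.17 over all its alternatives. The fold of Pp3c23_1470 moved by over 1.5 times when either DMSO library was left out, to a log2 change of -6.42 without DMSO 1 and -3.70 without DMSO 2.

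Among called loci with a maxMultiRatio of 0, the largest decrease, singled out after its value was seen, went from 59.4 ± 0.39 RPKM (n = 2) to 2.24 ± 0.47 RPKM (n = 3). Its log2 change was -4.47 (SE 0.19, limma adjusted p = 0.000937), and it rested on 8630 reads in DMSO and 471 in β-estradiol. It was -4.23 in the deeper and -4.59 in the shallower libraries.

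**Figure D3:**
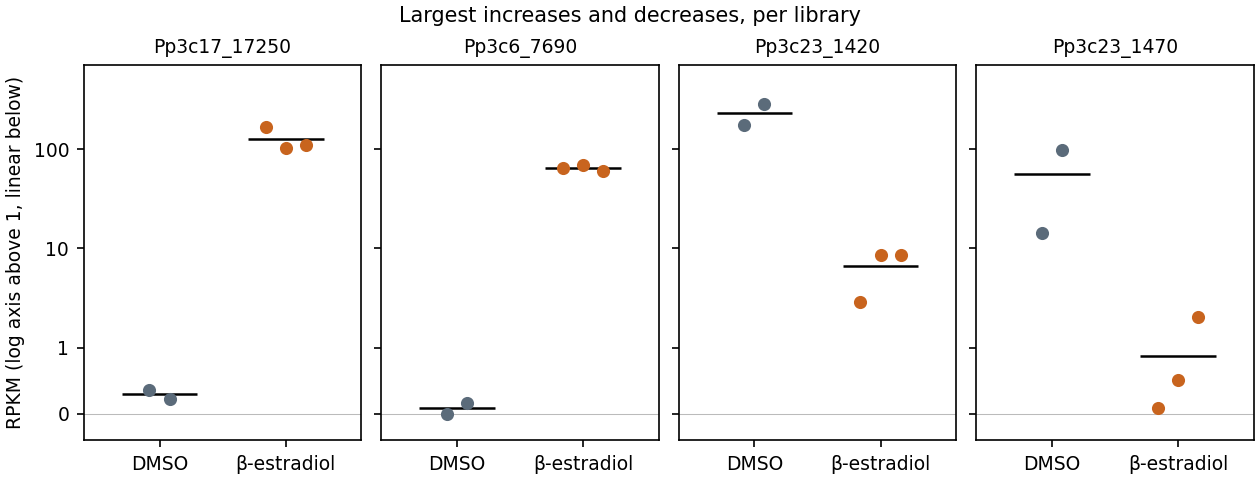
RPKM of the 2 loci with the largest increase and the 2 with the largest decrease, with a point per library and a horizontal line at the group mean; the vertical axis is logarithmic above 1 and linear below. For Pp3c17_17250 the β-estradiol libraries average 127 RPKM against 0.293 in DMSO, and for Pp3c23_1420 6.65 against 229.

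The prefix Pp3c14, chromosome 14 in this ID scheme, held 31 of the loci that rose, where 12.2 were expected (odds ratio 2.81, Fisher's exact test, p = 1.81e-06, adjusted p = 9.77e-05 over 54 tests). A run of 8 neighbouring loci was part of this. Without that run it held 23 among 761 tested (odds ratio 2.09, Fisher's exact test, p = 0.00214), which did not pass in its place among the 54 tests (adjusted p = 0.0923). Without β-estradiol 1, β-estradiol 2 and β-estradiol 3 in turn, it held 6, 2 and 1 rising loci, of 49, 17 and 17 that rose. It held more without DMSO 1, when far more loci were called in all, and about as many without DMSO 2. Pp3c14 held 769 of the 17429 tested loci. The 6 of 49 lie above that share, but 3 of the 6 belong to the run of 8, and no test was run. The 2 and 1 of 17 are too few to show whether the excess held. For the fits without a DMSO library expected numbers are not given. With the depth class as a term Pp3c14 held 100 against 75.4 expected (Fisher's exact test, p = 0.00346), which did not pass (adjusted p = 0.157 over 54 tests). In the fit without that term, none of the tests of other prefixes passed after adjustment. Fisher's exact test counts loci as independent, although neighbours often rose together. The next smallest adjusted p, 0.0923, was that of fewer rising loci under Pp3c18 and of more under Pp3c4.

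Loci that rose were often neighbours. There were 38 pairs of neighbouring tested loci that both rose, against a mean of 4.35 in 10000 random reassignments (permutation p = 1e-04, the smallest they can give, adjusted p = 2e-04 over 12 tests). These pairs formed 21 runs with 59 loci, or 21.4% of all loci that rose, and 10 of the 12 largest increases lay in a run. Loci that fell formed 39 neighbouring pairs against 15.2 by chance (permutation p = 1e-04, again the smallest, adjusted p = 2e-04), in 36 runs with 75 loci. Fewer neighbours were called without β-estradiol 1, 2 or 3 (8, 6 and 6 pairs that rose; 1, 0 and 0 that fell), when far fewer loci were called in all. Without DMSO 1 more pairs were counted, when far more loci were called in all. The 8, 6 and 6 rising pairs came from only 49, 17 and 17 rising loci. Chance gave a mean of 4.35 pairs with 276 rising loci, and it gives fewer with fewer calls. Rising pairs therefore exceeded chance in these fits as well, which share libraries with the full fit. How far they did is not given. For falling pairs, and for the fits without a DMSO library, the counts do not show whether pairs exceeded chance.

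The longest runs each held 8 rising loci. Under Pp3c14, between locus numbers 20870 and 21020, all 8 tested loci of 10 listed rose (limma adjusted p from 0.0055 to 0.0292). The 6 of them with reads in DMSO had log2 changes of 1.12 to 2.87, and for the 2 without a read the approximate bound was at least 3.85. The median over the 8 fitted values was 1.89 (median SE 0.22), or 2.20 with the 2 loci at their bound. Their levels were 0 to 5.87 RPKM in DMSO (n = 2) and 1.16 to 15.9 RPKM in β-estradiol (n = 3). Under Pp3c4, between locus numbers 6910 and 7070, all 8 tested loci of 10 listed rose (limma adjusted p from 0.00573 to 0.0316). The 7 of them with reads in DMSO had log2 changes of 1.46 to 2.77, and for the 1 without a read the approximate bound was 7.14. The median over the 8 fitted values was 2.08 (median SE 0.23), or 2.21 with that locus at its bound. Their levels were 0 to 1.88 RPKM in DMSO and 1.52 to 13.4 RPKM in β-estradiol. The longest run among 1000 random reassignments was 3. Of the nearest 16 tested loci around each run, 0 were called by limma or by voom, with log2 changes of -0.31 to 0.71 (median 0.10) under Pp3c14 and -0.40 to 1.01 (median 0.15) under Pp3c4. At an unadjusted p under 0.05, 2 of these loci were higher under Pp3c14 and 4 under Pp3c4, and 0 lower. With the depth class as a term, limma called 1 higher under Pp3c14, and 5 higher and 1 lower under Pp3c4. The loci directly next to a run are uncalled in the main fit by the definition of a run. Under Pp3c14 these changed by 0.02 and 0.06. Under Pp3c4 the flanking loci numbered 6830 to 6900 rose by 0.52 to 0.80, and those numbered 7080 to 7110 by 0.44 to 1.01. The flanking loci further out there lay between -0.40 and 0.15, so the calls do not show a sharp border. On the log2(RPKM + 0.5) scale, members were higher in both depth classes, by 1.06 or more under Pp3c14 and 1.34 or more under Pp3c4. Voom called 7 of the 8 members of each run. Without β-estradiol 1, 3 members of each run passed. Without β-estradiol 2 or without β-estradiol 3, 0 passed under Pp3c14 and 1 under Pp3c4, and the lowest log2 changes in any fit without a library were 0.97 and 1.29.

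**Figure D4:**
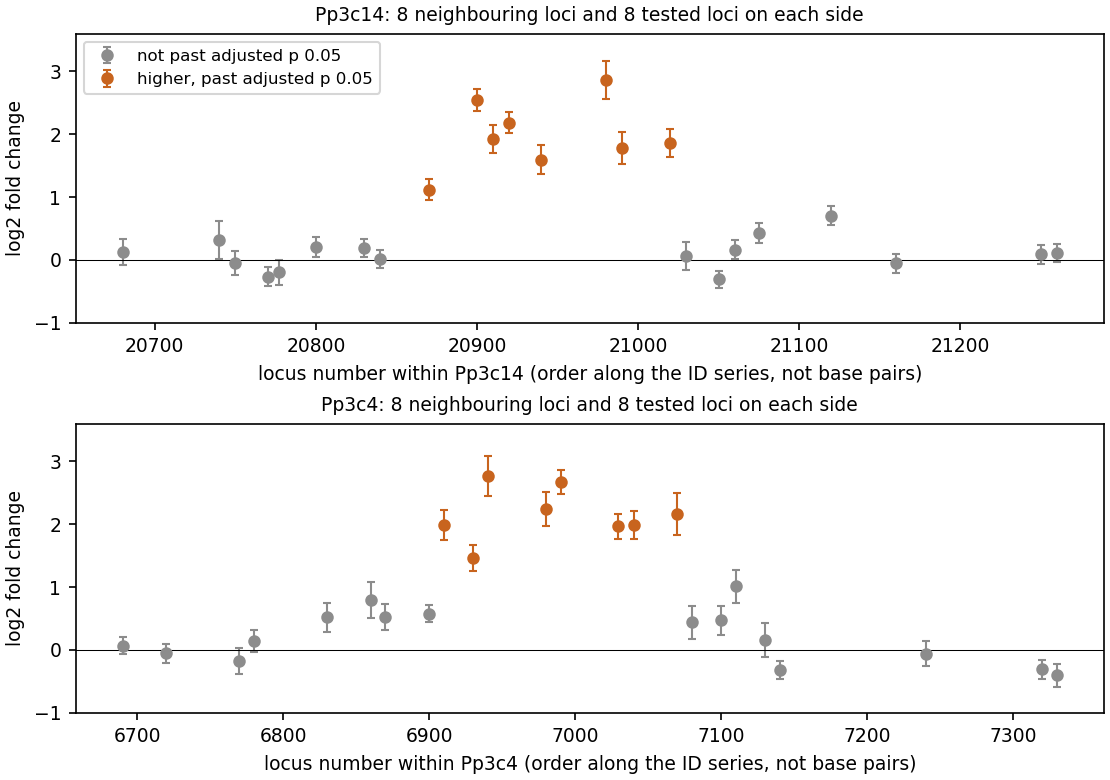
Log2 fold change (β-estradiol against DMSO, bars ± SE) of the 8 loci of the runs under Pp3c14 and Pp3c4 and of 8 tested loci on each side, against the locus number; members without a read in DMSO (2 under Pp3c14, 1 under Pp3c4) are drawn at fitted values, which are no bound. The run members (orange) lie between 1.12 and 2.87 under Pp3c14 and between 1.46 and 2.77 under Pp3c4, and the flanking loci (grey), between -0.31 and 0.71 under Pp3c14 and between -0.40 and 1.01 under Pp3c4, did not pass adjusted p 0.05.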

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

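The depth class as a term, voom on the recovered reads and the restriction to loci with a maxMultiRatio of 0 were chosen after seeing the data. The number of changed loci (790, with 276 higher and 514 lower) stayed within 1.5 times under 10 of 18 alternatives. These were both other pseudocounts, the higher filter (553), the TMM table (845), median scaling (894), quantile normalization (888), limma without trend and robust settings (776), the fit without DMSO 2 (781), voom (607) and loci with a maxMultiRatio of 0 (733). Without a filter it was 494 (156 higher, 338 lower) among 24719 loci. With the depth class as a term it was 4104 (1708 higher, 2396 lower), and 4440 (1826 higher, 2614 lower) with voom and the depth class. Leaving out 1 library gave 32 to 3762 changed loci, 17 to 1342 higher and 15 to 2420 lower. With 1 DMSO library left out, the other is assumed to vary like the β-estradiol libraries.

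With the replicate number as a block there were 1801 calls (584 higher, 1217 lower), of which 771 were shared with the fit without it. The block rests on 2 pairs, since β-estradiol 3 is alone in its block, and without β-estradiol 3 and without a block there were 32 calls. Deviations from the group means correlated at 0.615 for the libraries numbered 1. With 2 DMSO libraries their deviations mirror each other, so the 0.541 for those numbered 2 and the 0.406 of DMSO 2 with β-estradiol 3 are not separate evidence. With 2 pairs and no label that ties a number to a day or culture, the numbers were not taken as a pairing. The cause of the differences between settings was not tested. Higher loci made up 34.9% of calls, and 31.6 to 43.1% under the alternatives other than leaving out a library. They made up 36.6% without β-estradiol 1, but 53.1% of the 32 calls without β-estradiol 2 and of the 32 without β-estradiol 3. The 4 named loci kept their direction in every setting run. Pp3c23_1470 did not pass in 7 of 17 (adjusted p up to 0.17) and Pp3c23_1420 in 2 of 17. Neither has a value among loci with a maxMultiRatio of 0. Neighbouring pairs moved by over 1.5 times in 9 of 18 settings for rising and 9 for falling loci, and rising loci under Pp3c14 in 7. Depth limits the 16 loci with at most 3 reads in each DMSO library, whose fold changes depend on the pseudocount. Pp3c6_7690 was at 5.92 with a pseudocount of 1 and at 8.62 with 0.1 on the log2 scale, and at 9.73 with voom. Pp3c17_17250, which is not among these 16, moved as well, to 6.60, 8.33 and 8.71 in the same settings. The planned gene lists, the PpARFC2 check and the count models for deposited counts were not run.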

Other observations

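The tests of gene length, of the level ratio within pairs, of loci 5 positions apart, of likeness among neighbours and of the splits were chosen after the results were seen, as was the region under Pp3c23. A group of neighbouring loci fell together under Pp3c23, between locus numbers 1340 and 1480, which holds both named loci with the largest decrease. Of its 10 listed loci 7 were tested, and 6 fell, with log2 changes between -5.09 and -0.68 over the 7. A maxMultiRatio above 0.9 marks 8 of the 10 loci, so reads may be divided arbitrarily among them. Summed over the 10 loci, there were 14993 and 23438 reads in the DMSO libraries (0.0542 and 0.129% of reads in loci) and 235, 647 and 597 in the β-estradiol libraries (0.000862, 0.00346 and 0.0034%), a sum that reads exchanged within the group leave as it is. Among falling neighbours in general, pairs were 2.57 times chance, and 2.08 times among loci with a maxMultiRatio of 0 (permutation p = 1e-04, the smallest possible), which argues against shared reads as the whole cause. In a fit with the depth class as a term and lists of 514 loci each, neighbours lower after induction were 3 times chance and neighbours lower in the shallower libraries 2.79 times (2.19 and 2.25 times with lists of 825), in line with a general likeness of neighbouring loci.

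Rising neighbours were 8.74 times chance, and 7.77 times among loci with a maxMultiRatio of 0, which argues against shared reads as the whole cause. In 33 of the 38 rising pairs the weaker locus had over 10% of the stronger RPKM (median ratio 0.37 over the 38). Chance gave 4.35 pairs of any level, so stray reads from a single strong locus that stay under 10% do not account for these 33. Larger shares of stray reads stay open. The filter on low values also removes weak neighbours, which raises the share of such pairs. In only 4 pairs does it remove no more than loci under 1% of the stronger RPKM, and in 3 of these the weaker locus had over 10%. In a fit with the depth class as a term, neighbours higher after induction were 7.06 times chance and neighbours higher in the shallower libraries 3.49 times with lists of 276 loci, and 3.10 and 2.02 times with lists of 558, so a general likeness of neighbours stays open. Overlapping gene models stay open too, since no coordinates were used: rising loci 2 and 5 positions apart were 4.85 and 2.31 times chance (adjusted p = 0.0017 and 0.016), but the runs of 8 hold such pairs by construction, and without these runs loci 5 positions apart were 1.04 times chance (permutation p = 0.55). An effect of induction on a whole region, an effect of β-estradiol itself and a transgene inserted near a run were not tested.

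The libraries numbered 1 stood apart from the other 3 in both treatments. With treatment in the model, 1383 loci differed between the deeper and the shallower libraries (limma, adjusted p under 0.05), 558 higher and 825 lower in the shallower. Thinning the deeper libraries to the depth of the others kept 1310 of the 1383, which argues against the number of reads alone as the source of most of them. Levels are already scaled to depth, so thinning does not test anything else that goes with depth in these libraries. Removing each library's trend with gene length kept 1221, which argues against a length bias. A shared day, culture or library batch of the replicate 1 libraries stays open, because the labels give none, and no biological explanation was tested.

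Of the 10 splits of the 5 libraries into 2 and 3, only 1, the real one, gave as many as 790 calls. The highest of the others gave 1, and it follows the depth classes. The other splits leave the treatment difference within their groups, which lowers their calls in advance. Even the split by depth class gave 1, although 1383 loci differed by depth class with treatment in the model. The splits therefore do not show how many calls chance would give. With 10 splits no share under 0.1 is possible.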
